A study of Drosophila melanogaster with 13 samples.

How the data were processed

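Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole bodies of adult Drosophila melanogaster aged 2 to 3 days. The 3 fly lines expressed Pita, a zinc-finger architectural protein of insulators, in different forms. Pitawt carried the wild-type protein. PitaΔZ lacked the ZAD, the zinc finger-associated domain through which such proteins pair. PitaZ276 carried the ZAD-like domain of the human protein ZFP276 in its place. Each line was assayed with a FLAG antibody and with a Pita antibody. The labels give 2 libraries for each of the 6 combinations and 1 library made with preimmune serum, 13 libraries in all. Per the labels' protocols, chromatin was fixed in 1% formaldehyde for 15 min and sheared to fragments of 200 to 600 bp.

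The deposited files were 6 peak lists, 1 for each line and antibody. Per the submitters' processing notes, the tools were cutadapt, Bowtie2, Picard, bedtools, MACS2 and deepTools, and the genome build was dm6. No versions are given in the sources used here. Each list had 20 columns, in the layout that a test of irreproducible discovery rate (IDR) writes when it joins a pair of peak lists. Column 7 was taken as the fold enrichment over background computed by the authors' peak caller, a ratio. Column 9 was taken as the −log10 q-value, and 2 further columns as the −log10 p-value in each of the joined lists, all as deposited. Column 12 was taken as the −log10 of the global IDR. These readings rest on the layout and on the values, since the files have no header. The names of the lists set each against the preimmune library. Which library stood behind which of the joined lists is not given in the sources used here. The lists held no read counts, so the depth per library is unknown.

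Because a list joins a pair of peak lists, each line and antibody gave a single set of peaks and folds with no spread between replicates. The −log10 p columns of the joined lists were compared with each other, but were not treated as replicates, since they are not known to be separate libraries. Shares of peaks are therefore given with exact Clopper-Pearson 95% intervals, which cover counting error only. No test between lines with replicates was possible. Folds were used only to rank or describe peaks within a list. Peaks were called shared when they overlapped by at least 1 bp. Overlaps were set against 1000 random placements of the second list on the same chromosomes. Dual-antibody sites were Pitawt FLAG peaks that met a Pitawt Pita peak, and a site counted as present in another line when either antibody list of that line met it.

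Gene positions came from the RefSeq table of Release 6, the assembly that dm6 names, with 17684 genes on chromosomes 2L, 2R, 3L, 3R, X and 4. That table has no strand and no exons. The planned annotation by transcription start site was therefore replaced by distance to either end of a gene, with a window of 500 bp, and summits farther away were divided into those inside and those between genes. A planned search for sequence motifs was not run, as no genome sequence was used here. Occupancy of 17 gene lists, fixed before the data were examined, was tested with two-sided Fisher's exact tests on genes with a summit within 500 bp of either end, with Benjamini-Hochberg adjustment over all lists and peak sets. That test treats genes as units and describes a peak set; it does not compare lines.

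The sites named were set by a rule fixed before the data were examined. It took the 8 dual-antibody sites with the highest Pitawt FLAG fold in each of 4 classes. It added up to 5 sites per altered line found with both of its antibodies and with neither in Pitawt. It further took 9 fixed genes with 2 kb on each side, the interval between abd-A and Abd-B, and up to 4 examples per gene list. Sites were named by the gene with the nearest end. Sites named under other observations were chosen after their values were seen.

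Alternatives fixed beforehand were a 50% reciprocal overlap, summits within 100 bp, −log10 q of at least 5 or 10, a fold of at least 4, equal list lengths, chromosome arms only, other gene end windows and a protein-coding background. Further alternatives were chosen after seeing the data. The overlap code was tested on simulated data, in which 1785 randomly placed peaks were compared with a copy holding 10 to 90% of them; it found 100% of the planted overlaps and called at most 4.47% of the rest. In 20 simulated peak sets with 25 planted ribosomal protein genes the list was found in 20, and random peaks gave 1 call in 340 tests. The random peaks were spread evenly over each chromosome, and planted summits lay on gene starts. That rate of calls therefore does not calibrate the gene list tests for peaks that cluster near gene ends. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for figures.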

Results

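Pita occupancy was mapped by ChIP-seq in whole adult flies of the Pitawt, PitaΔZ and PitaZ276 lines, with 2 antibodies and 2 libraries per line and antibody. The comparison asks how far the sites bound by wild-type Pita are still called when the ZAD is removed, and when a human ZAD-like domain stands in its place. The lists held 1792 peaks for Pitawt FLAG and 1195 for Pitawt Pita. PitaΔZ gave 685 FLAG peaks and 797 Pita peaks. PitaZ276 gave 1243 FLAG peaks and 492 Pita peaks. The depth of the libraries is unknown, so a difference in list length is not by itself a difference in binding. The authors' fold enrichment had a median of 10.5 in Pitawt FLAG, 29.5 in PitaΔZ FLAG and 9.90 in PitaZ276 FLAG, values that describe each list alone.

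Within a line, almost all peaks of the shorter list shared at least 1 bp with the longer one in Pitawt, PitaΔZ and PitaZ276. Of the Pitawt Pita peaks, 97.9% (95% interval 96.9 to 98.6) met a Pitawt FLAG peak, while 63.8% of the longer FLAG list met a Pita peak. In PitaΔZ, 95.5% of FLAG peaks (93.6 to 96.9) met a Pita peak, and in PitaZ276, 99.8% of Pita peaks (98.9 to 100.0) met a FLAG peak. In the reverse direction, 82.7% of PitaΔZ Pita peaks (79.9 to 85.2) met a FLAG peak, and only 38.1% of PitaZ276 FLAG peaks (35.3 to 40.8) met a Pita peak. With 50% reciprocal overlap the shares of the shorter lists were 70.8% in Pitawt, 70.4% in PitaΔZ and 21.1% in PitaZ276, and with summits within 100 bp they were 92.8%, 88.6% and 81.1%. At 1 bp, the highest of the random placements for the shorter lists were 4.29%, 2.94% and 4.50%. The joined columns matched to different degrees. The −log10 p of the joined lists correlated across peaks with a Spearman rho of 0.982 in Pitawt FLAG, 0.992 in PitaΔZ FLAG and 0.993 in PitaΔZ Pita, but 0.872 in Pitawt Pita, 0.896 in PitaZ276 FLAG and 0.586 in PitaZ276 Pita. In PitaZ276 Pita the median −log10 p was 16.8 in the first joined list and 537 in the second. Every share that uses the PitaZ276 Pita list carries this mismatch.

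The PitaΔZ Pita list lacked the strongest PitaΔZ sites. All 10 of the strongest PitaΔZ FLAG peaks were absent from it, as were 20 of the strongest 35, whereas 31 of all 685 were absent. Those 20 were called in the Pitawt Pita list and in the PitaZ276 Pita list. Among the sites concerned were those at Rala, a small GTPase gene, at ATPsynC, which encodes an ATP synthase subunit, and at Socs36E, a regulator of JAK/STAT signalling. None of the strongest 89 Pitawt FLAG peaks and none of the strongest 62 PitaZ276 FLAG peaks was missing from the Pita list of its own line. Every share that uses the PitaΔZ Pita list carries this gap.

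**Figure D1:**
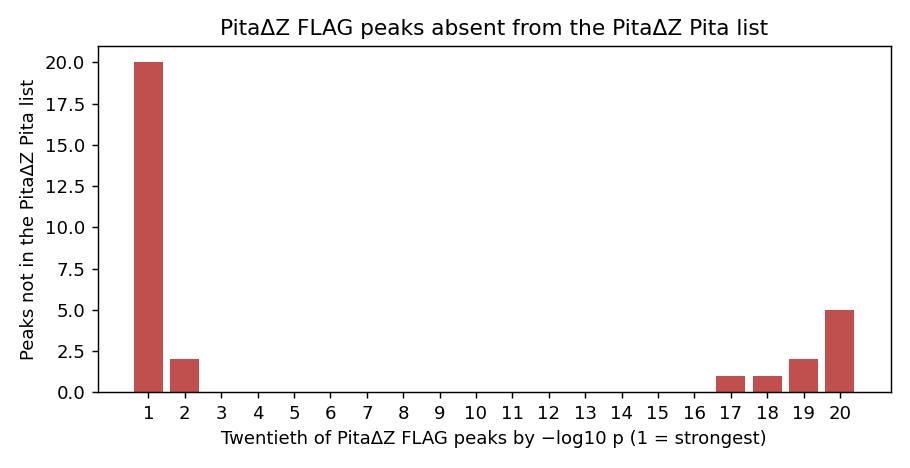
PitaΔZ FLAG peaks absent from the PitaΔZ Pita list (count, vertical axis), with the 685 FLAG peaks ordered by −log10 p and divided into 20 bins of 34 or 35 (horizontal axis, 1 = strongest). Bin 1 held 20 of the 31 absent peaks.

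With the FLAG antibody, fewer Pitawt peaks were called in PitaΔZ than in PitaZ276. PitaΔZ held 37.3% of them (35.1 to 39.6) and PitaZ276 held 62.1% (59.8 to 64.3). With the Pita antibody the order was the opposite, with 53.2% (50.3 to 56.1) in PitaΔZ and 37.8% (35.1 to 40.6) in PitaZ276. The deposited lists do not share a threshold, as the smallest −log10 IDR was 2.00 to 2.02 in Pitawt FLAG and both PitaΔZ lists and 1.30 to 1.31 in the other 3. With at least 2 in every list the Pita shares were 62.5% in PitaΔZ and 21.9% in PitaZ276. At that cut the PitaZ276 Pita list held only 201 peaks, and all 201 met a Pitawt Pita peak. The length of that list therefore limits its share, and the order with the Pita antibody is not read as a difference in binding. When every list was shortened to its strongest 492 peaks, PitaZ276 held more with either antibody, 84.6% against 72.6% for FLAG and 69.3% against 60.8% for Pita. The settings tried include the main one and are not separate checks. Over them, PitaZ276 held more Pitawt FLAG peaks in 10 of 10 and more Pitawt Pita peaks in 1 of 10. It held more of the dual-antibody sites described next in 11 of 12. In the reverse direction, 97.2% of PitaΔZ FLAG peaks (95.7 to 98.3) and 88.9% of PitaZ276 FLAG peaks (87.0 to 90.6) met a Pitawt FLAG peak. With the Pita antibody, 79.8% of PitaΔZ peaks (76.8 to 82.5) and 94.1% of PitaZ276 peaks (91.6 to 96.0) met a Pitawt Pita peak, which left 161 of the 797 PitaΔZ peaks outside that list. Most of the 797 met the longer Pitawt FLAG list, at 742 peaks (93.1%, 91.1 to 94.8). PitaΔZ FLAG peaks were contained almost entirely in the PitaZ276 FLAG list, at 98.4% (97.1 to 99.2).

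Pitawt had 1143 sites called with both antibodies. Of these, 654 (57.2%, 54.3 to 60.1) were called with either antibody in PitaΔZ and 863 (75.5%, 72.9 to 78.0) in PitaZ276. Under this rule the sets were nested, with 651 sites called in both other lines, 212 in PitaZ276 and not PitaΔZ, 3 in PitaΔZ and not PitaZ276, and 277 in neither. Of the 489 sites not called in PitaΔZ, 212 (43.4%, 38.9 to 47.9) were called in PitaZ276. The order, the nesting and this share all depended on the antibody rule. When a site had to be called with both antibodies, PitaΔZ held 49.0% and PitaZ276 held 39.4%, PitaZ276 held 67.5% of the 560 PitaΔZ sites, and 12.3% of the 583 others were called in it. In PitaZ276, 413 sites were called with FLAG alone and 0 with Pita alone, where the Pita list had 492 peaks against 1243 for FLAG.

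Sites called in all 3 lines included the strongest in the wild type. The site between CG34130 and CG6073 (dm6, 3R:26187920 to 26189893), 97 bp from the end of CG34130, had a Pitawt FLAG fold of 227 and ranked second by p. The strongest by p lay between Rala and Tlk on X, from 3719249 to 3720938, with a fold of 219. The site at fzr, an activator of the anaphase-promoting complex, had a fold of 178 and lay 113 bp from the gene end. ATPsynC also had 178, at 91 bp. Sites at Tmhs, Men-b, which encodes a malic enzyme, Socs36E and nemy had folds of 155, 152, 142 and 141. Of these 8 sites, the summits at Tmhs and nemy lay inside a gene, and the other 6 lay in none. Those at CG34130, Rala, ATPsynC, Tmhs, Men-b and Socs36E were called in PitaΔZ with FLAG only.

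Sites called in PitaZ276 and not in PitaΔZ were weaker in the wild type. The highest, from 9570639 to 9572237 on 2L, had a Pitawt FLAG fold of 51.2 and a PitaZ276 FLAG fold of 10.9. Its summit lay inside brwl, 1966 bp from the end of Mtpalpha, a subunit gene of the mitochondrial trifunctional protein. The next were at Fmo-1 (fold 39.3), which encodes a flavin-containing monooxygenase, Obp47b (39.1), an odorant-binding protein gene, and the Hox gene pb (38.8), with a summit inside pb, 1259 bp from its end. Those at CG1598, CG17350, mthl9 and lncRNA:CR44097 had folds of 36.9, 36.1, 34.5 and 34.3. The summit named for Obp47b lay inside CG7741, that for mthl9 inside Ptpmeg and that for lncRNA:CR44097 inside Hsp68. The CG17350 summit lay in no gene, 2111 bp from the end of CG17350. Sites at Obp47b and pb were called in PitaZ276 with FLAG only.

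Sites called in neither other line were weaker still in the wild type. The highest lay inside rho-6, a rhomboid family gene (2L, 12130587 to 12131309, fold 37.8), inside FucTA, a fucosyltransferase gene (fold 37.6), at the checkpoint kinase gene grp (36.4) and inside CenG1A (31.3). Others were at lncRNA:CR45966 (28.5), at AstC, which encodes the neuropeptide allatostatin C (24.0), inside haf, 5859 bp from the end of nis (23.5), and inside grh, 4776 bp from the end of asRNA:CR45270 (21.6). The summit named for grp lay inside CR43669. The 3 sites called in PitaΔZ and not PitaZ276 were nearest to CG10651, IA-2 and Inos and lay between genes, with Pitawt FLAG folds of 17.9, 8.69 and 6.67.

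Sites called with both antibodies of a line and with neither in Pitawt were rare. In PitaΔZ, 15 of 654 sites called with both antibodies (2.29%, 1.29 to 3.75) met no Pitawt peak. The strongest were at CG31886 (FLAG fold 13.7), between Spn and msn (12.5), at Arpc4, an Arp2/3 complex gene (12.2), inside mtt (10.8) and at Cnx99A, a calnexin gene (10.5). All but the site at CG31886 were also called with FLAG in PitaZ276. In PitaZ276, 1 of 473 sites met no Pitawt peak (0.211%, 0.00535 to 1.17), at CG12134 on 2R, with a FLAG fold of 19.9. Peaks of a single list that met no Pitawt peak, on the named chromosomes, were 18 of 681 in PitaΔZ FLAG and 50 of 789 in PitaΔZ Pita. They were 135 of 1237 in PitaZ276 FLAG, with a median fold of 3.98, and 1 of 489 in PitaZ276 Pita.

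Strong wild-type peaks were called in the other lines far more often than weak ones. Of the strongest 359 Pitawt FLAG peaks, with folds of 26.1 to 227, 90.3% (86.7 to 93.1) were called in PitaΔZ and 98.6% (96.8 to 99.5) in PitaZ276. In the middle bin, with folds of 8.30 to 13.5, the shares were 26.3% and 67.6%. In the weakest bin they were 4.75% (2.79 to 7.49%) and 68 of 358 (95% interval 15.1 to 23.4%). With the Pita antibody the shares fell from 79.9% to 21.8% in PitaΔZ and from 85.8% to 4.60% in PitaZ276. The PitaΔZ Pita value for the strongest bin includes the gap described above.

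**Figure D2:**
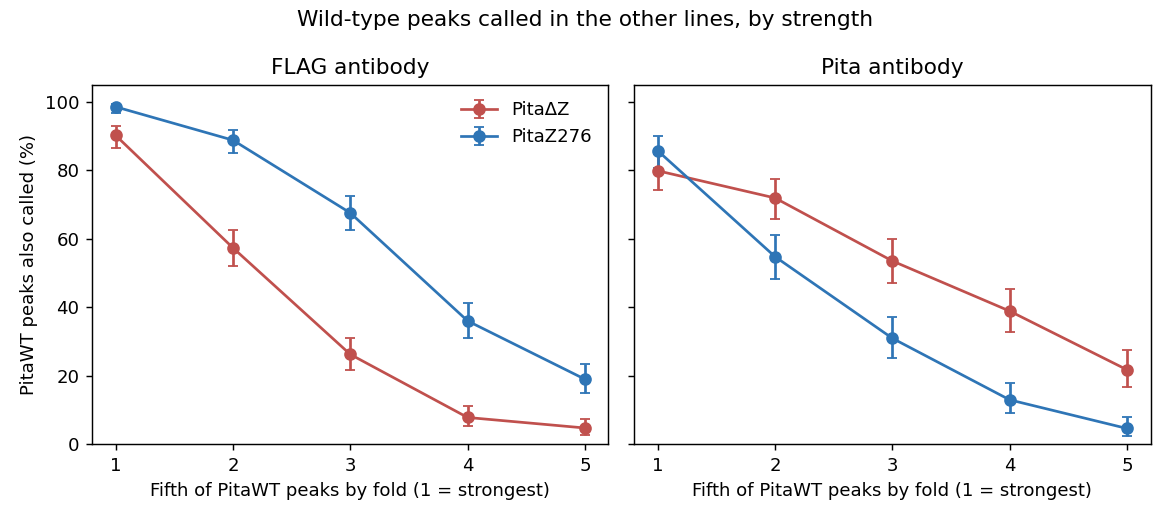
Share of Pitawt peaks also called in PitaΔZ (red) and PitaZ276 (blue), in percent, for 5 equal bins of Pitawt peaks ordered by the authors' fold (1 = strongest), with the FLAG antibody on the left and the Pita antibody on the right. Points are shares and bars are exact 95% intervals for counting error; FLAG shares fell from 90.3% to 4.75% in PitaΔZ and from 98.6% to 68 of 358 peaks in PitaZ276.

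Pita sites lay near gene ends. Within 500 bp of a gene end were 55.6% of Pitawt FLAG summits (53.2 to 57.9), 70.6% of PitaΔZ FLAG summits (67.1 to 74.0) and 61.9% of PitaZ276 FLAG summits (59.2 to 64.6). No random placement exceeded 22.3% for these lists. The share was 57.1% for Pitawt Pita, 68.4% for PitaΔZ Pita and 68.7% for PitaZ276 Pita. Among dual-antibody sites it was 71.0% (67.3 to 74.5) for those called in both other lines, 50.2% (43.3 to 57.2) for those called in PitaZ276 and not PitaΔZ, and 33.9% (28.4 to 39.8) for those called in neither, 53.8% of which lay inside genes. These classes also differed in strength, with median Pitawt FLAG folds of 26.5, 13.0 and 8.58. Within 5 fold bins, from strongest to weakest, PitaΔZ held 97.6%, 89.9%, 68.8%, 44.8% and 13.8% of sites near a gene end and 91.4%, 74.3%, 47.5%, 23.4% and 9.29% of the others, with overlapping intervals in the strongest and weakest bins. In PitaZ276 the shares were 98.8% against 98.3% in the strongest bin, 93.0% against 75.8% in the middle bin and 39.1% against 21.4% in the weakest.

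**Figure D3:**
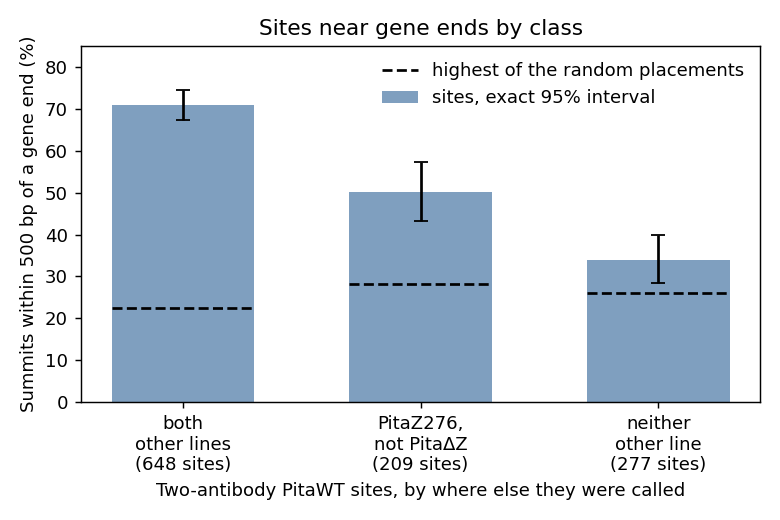
Share of dual-antibody Pitawt sites with a summit within 500 bp of a gene end (percent, vertical axis) for sites called in both other lines, in PitaZ276 and not PitaΔZ, and in neither. Bars are 71.0%, 50.2% and 33.9% with exact 95% intervals for counting error, and dashed lines mark the highest of 1000 random placements.

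Ribosomal protein genes were the gene list enriched in every line. A Pitawt FLAG summit lay within 500 bp of an end of 25 of the 93 genes, against 8.41% of other genes (odds ratio 4.00, adjusted p = 6.35e-06, Fisher's exact test). By the same exact test the count was 18 in PitaΔZ FLAG (odds ratio 5.38, adjusted p = 4.87e-06) and 25 in PitaZ276 FLAG (5.26, adjusted p = 8.94e-08). It was 20 in Pitawt Pita, 22 in PitaΔZ Pita and 13 in PitaZ276 Pita. Examples called in all 6 lists were RpS15Aa, RpL22, RpL17 and RpS14a, with Pitawt FLAG folds of 79.2, 72.4, 61.5 and 51.7. The dual-antibody sites called in both other lines reached 17 of the 93 genes. This list was among those set beforehand to look for signal at highly transcribed genes. The others so set, for tRNAs, snRNAs and snoRNAs and the main tissues, did not pass the threshold for enrichment. The tissue lists held only 11 to 18 genes, too few to show its absence. In Pitawt FLAG their odds ratios were 3.59 (neuronal), 1.34 (germline), 0.768 (muscle) and 0 (fat body or gut). Expression was not measured, and whether the enrichment reflects Pita binding or signal at highly transcribed genes was not tested. The classes called in PitaZ276 and not PitaΔZ and in neither line reached 161 and 136 genes of any kind, too few to show enrichment or its absence. Genes for snRNAs and snoRNAs were reached less often than other genes in Pitawt FLAG (10 of 289, odds ratio 0.381, Fisher's exact test, adjusted p = 0.0127) and in PitaΔZ FLAG (1 of 289, odds ratio 0.0752, adjusted p = 0.00102). By the same exact test they also passed in PitaΔZ Pita (1 of 289, adjusted p = 0.000239), in PitaZ276 Pita (1 of 289, adjusted p = 0.0341) and in the sites called in both other lines (1 of 289, adjusted p = 0.00208), but not in PitaZ276 FLAG (10 of 289, adjusted p = 0.231), Pitawt Pita (8 of 289, adjusted p = 0.157) or the dual-antibody sites (7 of 289, adjusted p = 0.111). With a protein-coding background that list could not be tested, and with windows of 200 or 1000 bp the depletion passed the threshold in neither of these FLAG lists. The test takes no account of gene length, although short genes offer less sequence within 500 bp of their ends. Nor does it allow for genes that share a peak. The 4 examples of this list all met 1 peak (3R, 5595524 to 5597368). That peak was called in both Pitawt lists and in PitaZ276 FLAG, and not in the other lists. The counts are therefore not of independent sites.

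The other 15 lists did not pass the threshold in any peak set. In Pitawt FLAG these were the genes of mitochondrial ribosomal proteins (8 of 73), oxidative phosphorylation (10 of 80), the proteasome (9 of 48), translation factors (9 of 51) and nuclear tRNAs (18 of 295). Replication origin factors had 4 of 22, architectural proteins 4 of 33, Hox and segmentation genes 0 of 27, Polycomb and trithorax genes 2 of 23, and chromatin modifiers 3 of 17. Circadian genes had 0 of 9, muscle genes 1 of 15, neuronal genes 3 of 12, germline genes 2 of 18 and fat body or gut genes 0 of 11. Individual sites were strong all the same, such as those at mRpL13 (fold 67.3), UQCR-Q (74.6), trx (71.3), the topoisomerase gene Top2 (65.7) and eIF4G2 (42.8).

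In the bithorax complex, which holds the Hox genes of the posterior body, the order of neighbouring sites differed in PitaΔZ. A site inside Abd-B (3R, 16969395 to 16970744) was called in all 6 lists. Its FLAG folds were 123 in Pitawt (rank 13 of 1792), 106 in PitaΔZ (rank 55 of 685) and 60.4 in PitaZ276 (rank 20 of 1243). Such folds describe each list alone. Between abd-A and Abd-B, the Pitawt FLAG list had peaks with summits at 16869381 (fold 22.6, rank 436 of 1792) and 16899571 (fold 40.0, rank 182). In PitaΔZ FLAG the peak on the abd-A side was the stronger, with a fold of 80.6 (rank 96 of 685) against 18.2 (rank 437). PitaΔZ Pita showed the same order, with 61.2 against 8.31, and Pitawt Pita the wild-type one, with 14.0 against 46.6. PitaZ276 FLAG had 10.4 against 27.3, and PitaZ276 Pita had no peak at the former. The reversal has no replicate test, as the columns joined in a list are not known to be separate libraries.

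**Figure D4:**
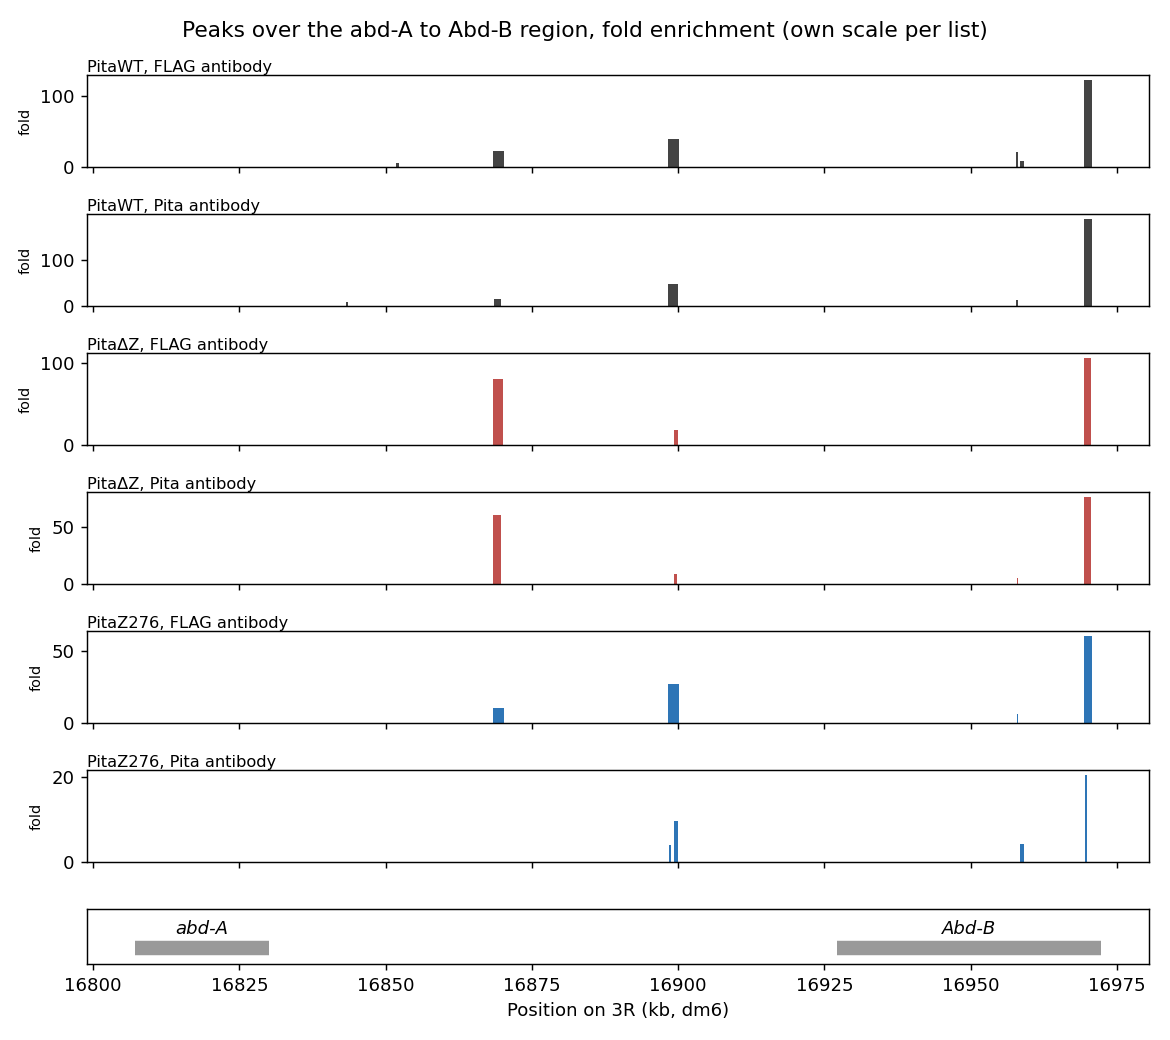
Peaks from abd-A to Abd-B on 3R (horizontal axis, kb, dm6), with 1 panel per line and antibody; bars span each peak and their height is the authors' fold enrichment, on its own scale in each panel. Of the pair of main peaks between the genes, the right one is higher in both Pitawt panels and the left one in both PitaΔZ panels.

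Of the other fixed genes, Orc4, which encodes an origin recognition complex subunit, had a peak at its end in all 6 lists. Its FLAG folds were 31.7 in Pitawt (rank 274 of 1792), 38.8 in PitaΔZ (rank 261 of 685) and 26.4 in PitaZ276 (rank 185 of 1243). Folds here describe each list alone and are not compared between lines. A peak inside pita itself was called in every list but PitaZ276 Pita, with a Pitawt FLAG fold of 11.8. A peak beside Ubx was called with FLAG in all 3 lines and with the Pita antibody in PitaΔZ alone. Its FLAG folds were 8.90 in Pitawt (rank 1025 of 1792), 13.2 in PitaΔZ (rank 498 of 685) and 7.69 in PitaZ276 (rank 729 of 1243). CTCF had 1 peak within 2 kb, in Pitawt FLAG (fold 4.66). No list had a peak within 2 kb of abd-A, Cp190, su(Hw) or eve.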

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

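In the 3 patterns weighed below, the tests of the reproducibility filter, of equal strength, of a single pool of reads, of site strength and of an effect without the ZAD were chosen after the results were seen.

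Peaks outside the named chromosomes, on unplaced or random sequences and in 1 case the mitochondrial genome, numbered 7 in Pitawt FLAG, 6 in Pitawt Pita, 4 in PitaΔZ FLAG, 8 in PitaΔZ Pita and 6 in PitaZ276 FLAG. They are signal in sequences left out of the annotation, listed where the count exceeded a floor of 3 per list; the list totals and overlap shares include them.

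The FLAG and Pita lists of a line differed in the share of dual-antibody Pitawt sites that they held. In PitaΔZ the FLAG share minus the Pita share was -3.67 percentage points, with 26 sites found by FLAG alone and 68 by Pita alone (exact binomial test, two-sided, p = 1.73e-05). In PitaZ276 it was 36.1 points, with 413 against 0 (exact binomial test, p = 9.45e-125). The direction in PitaZ276 was set by the lists. Its Pita list had 492 peaks against 1243 for FLAG, and 491 of the 492 met a FLAG peak. The sites found by FLAG alone in PitaΔZ include sites of the gap in its Pita list, such as those at Rala and ATPsynC. That gap covered 20 of the strongest 35 PitaΔZ FLAG peaks. These tests treat sites as units and compare peak lists, so they cannot separate the antibody from the length or quality of its list.

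The strongest PitaΔZ FLAG sites were missing from the PitaΔZ Pita list. A weaker response of the Pita antibody at those sites stays open: FLAG and Pita −log10 p rose together (Spearman rho 0.740) over the 115 sites called with both in the strongest of 5 bins of the FLAG list, but the missing sites have no Pita value. In the strongest of 5 bins of the PitaΔZ Pita list the −log10 IDR fell as −log10 p rose (rho -0.859), while the lowest rho in the other 5 lists was 0.679. The authors' reproducibility filter is therefore a candidate cause of the gap. No biological explanation was tested.

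The joined lists agreed far more closely in Pitawt FLAG, PitaΔZ FLAG and PitaΔZ Pita than in the other 3. At a −log10 p of 50 to 200 in the first column, the smallest SD of the log2 ratio in the other lists was 2.18 times the largest in the close ones. Strength in the first column therefore does not account for the closer agreement. The second column was not matched, and in PitaZ276 Pita its median −log10 p was 537 against 16.8 in the first, so strength is not excluded. A stricter filter does not account for the agreement, because with −log10 IDR of at least 2 the highest rho in the other lists was 0.890. Whether the close lists come from 1 pool of reads split in 2, or from well matched libraries, cannot be told apart, since both give a median log2 ratio near 0 (at most 0.0263 from 0 in the close lists), and the reads were not used here. The close lists were also those with a smallest −log10 IDR of 2.00 to 2.02, against 1.30 to 1.31 in the others. They may therefore have been processed differently, which does not decide between the sources.

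Dual-antibody sites near gene ends were called in PitaΔZ more often than others. Within 5 fold bins the difference was 14.2 percentage points and the highest of 100000 permutations was 12.3, so binning by fold did not remove it. The fold is a single value per site without replicates, so the test cannot exclude strength that the fold does not capture. High transcription stays open. Sites near genes of the ribosomal protein, tRNA, snRNA and snoRNA, muscle, neuronal, germline and fat body or gut lists were left out (13.7 points, highest permutation 10.6). That removed only 39 of 1137 sites, and expression was not measured. PitaZ276 showed 12.3 points (highest permutation 9.16), but it lacks the ZAD of Pita too, so an effect of losing that domain stays open. Differences in chromatin accessibility, which may accompany gene ends, remain untested.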

How the results depend on the processing

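No paired analysis was possible because each line and antibody has a single list, whose columns carry no replicate numbers; for the same reason no replicate could be left out. The search for motifs was not run. The depth of the libraries is unknown and limits every comparison of list lengths. Alternatives using IDR, the coordinates of the second joined list, the rule for presence, 40 bins or sites left out were chosen after seeing the data. PitaZ276 held more Pitawt FLAG peaks than PitaΔZ in 10 of 10 settings. For Pitawt Pita peaks PitaΔZ held more in 9 of 10, the exception being equal list lengths. For dual-antibody sites PitaZ276 held more in 11 of 12, the exception being presence in both antibody lists. These counts include the main setting and are not separate checks. A −log10 q of at least 5 removed no peak from any FLAG list. In the main setting, every dual-antibody site called in PitaZ276 was in its FLAG list. In the 6 lists and the dual-antibody sites, the only sets to which the alternatives were applied, ribosomal protein genes kept odds ratios of 3.38 to 6.54 and stayed past the threshold. Where a value below left its main 95% interval, the cause was not tested, except that a stricter overlap or threshold can only lower the number of matches or peaks.

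With 50% reciprocal overlap, 70.8% of Pitawt Pita peaks met FLAG, 70.4% of PitaΔZ FLAG met Pita and 21.1% of PitaZ276 Pita met FLAG. Pitawt FLAG peaks were found in PitaΔZ at 30.0% and PitaZ276 at 54.5%, and the reverse shares were 78.5% and 78.6%. For Pita they were 42.6% and 23.4%, reverse 63.9% and 56.9%. Dual-antibody sites were at 47.0% in PitaΔZ and 67.7% in PitaZ276, and 92.5% of those in PitaΔZ were in PitaZ276.

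With summits within 100 bp, the antibody shares were 92.8%, 88.6% and 81.1%. Pitawt FLAG peaks were at 34.9% and 54.1%, reverse 91.4% and 78.0%. Pitawt Pita peaks were at 30.5% in PitaZ276, and reverse shares were 76.2% for PitaΔZ and 74.0% for PitaZ276. Dual-antibody sites were at 68.7% in PitaZ276, with 37.9% of those not in PitaΔZ and 92.9% of those in PitaΔZ. The weakest Pitawt FLAG bin was at 2.51% in PitaΔZ and 14.0% in PitaZ276, and the strongest at 94.2% in PitaZ276. For Pita, the strongest and weakest bins were at 79.1% and 1.67% in PitaZ276.

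With equal list lengths, the antibody shares were 86.2%, 90.7% and 84.6%. Pitawt FLAG peaks were at 72.6% and 84.6%, reverse 72.8% and 83.7%, and Pitawt Pita peaks at 60.8% and 69.3%, reverse 60.8% and 70.7%. There were 420 dual-antibody sites, 76.4% in PitaΔZ and 89.0% in PitaZ276, with 55.6% of those not in PitaΔZ.

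With −log10 IDR of at least 2, the antibody shares were 99.8% for Pitawt and 100% for PitaZ276. Pitawt FLAG peaks were at 57.3% in PitaZ276, reverse 93.0%. Pitawt Pita peaks were at 62.5% and 21.9%, reverse 72.0% and 100%, the last of only 201 PitaZ276 Pita peaks. Dual-antibody sites were at 66.0% and 79.4%. With a fold of at least 4, 93.1% of PitaΔZ FLAG peaks met Pita, Pitawt FLAG peaks were at 58.1% in PitaZ276 (reverse 93.4%), Pitawt Pita peaks at 49.0% and 30.4% (reverse 84.0% and 96.1%), and dual-antibody sites at 53.8% and 71.0%, with 37.6% of those not in PitaΔZ. With −log10 q of at least 10, 100% of PitaZ276 Pita peaks met FLAG, Pitawt FLAG peaks were at 58.8% in PitaZ276 (reverse 92.5%), Pitawt Pita peaks at 49.6% and 24.4% (reverse 83.1% and 96.7%), and dual-antibody sites at 54.1% and 72.4%. With −log10 q of at least 5, Pitawt Pita peaks were at 33.2% in PitaZ276.

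With presence in both antibody lists, dual-antibody sites were at 49.0% in PitaΔZ and 39.4% in PitaZ276, with 12.3% of those not in PitaΔZ and 67.5% of those in it. With FLAG only, PitaΔZ held 51.3%, and 50.1% of the rest were in PitaZ276.

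With gene end windows of 200 and 1000 bp, the classes called in both other lines, in PitaZ276 and not PitaΔZ, and in neither had 56.0% and 80.4%, 22.0% and 63.6%, and 13.7% and 50.9%. The lists had 34.6% and 68.0% (Pitawt FLAG), 38.4% and 69.1% (Pitawt Pita), 53.0% and 79.9% (PitaΔZ FLAG), 50.6% and 77.1% (PitaΔZ Pita), 39.0% and 72.9% (PitaZ276 FLAG), and 50.1% and 76.5% (PitaZ276 Pita). Depletion of snRNA and snoRNA genes was less stable. For Pitawt FLAG, PitaΔZ FLAG, PitaΔZ Pita and PitaZ276 Pita the count of depleted gene lists fell from 1 to 0 with windows of 200 bp (except PitaΔZ Pita) or 1000 bp and, as that list then has no members, with a protein-coding background. With −log10 q of at least 10 it fell to 0 in PitaZ276 Pita and rose to 1 in PitaZ276 FLAG. Within 40 bins the location difference was 13.8 points by fold, 14.2 by FLAG p and 23.7 by Pita p in PitaΔZ, and 10.7, 9.84 and 20.5 in PitaZ276.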

Other observations

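With the FLAG antibody, the order of strength of shared sites differed more from Pitawt in PitaΔZ than in PitaZ276. Over the 663 sites common to the 3 FLAG lists, −log10 p correlated between Pitawt and PitaΔZ with a Spearman rho of 0.615 to 0.621 across pairs of columns, and between Pitawt and PitaZ276 with 0.846 to 0.882. The columns within a list correlated at 0.992 in Pitawt, 0.993 in PitaΔZ and 0.835 in PitaZ276. For the Pita antibody, over 404 sites, Pitawt against PitaΔZ gave 0.403 to 0.443 and Pitawt against PitaZ276 gave 0.586 to 0.901. Within lists the columns gave 0.893 in Pitawt, 0.994 in PitaΔZ and 0.611 in PitaZ276, so the Pita values for PitaZ276 depend on the column. These values are across sites, which are not independent replicates.

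Of the 378 dual-antibody sites in all 6 lists, 376 lay on the named chromosomes, and among these 33 ranked above the middle in every Pitawt column and below it in every PitaΔZ column, and 31 did the reverse. Examples, chosen after their values were seen, are sites near CG11905, Psi, CG13707, the Argonaute gene AGO2, the Frizzled receptor gene fz2 and Top2 among the former. Among the latter are sites near Polr2E, an RNA polymerase subunit gene, dre4, which encodes a subunit of the histone chaperone FACT, Nap1, a histone chaperone gene, and Syx1A. Of the former, 51.5% (33.5 to 69.2) lay within 500 bp of a gene end, and of the latter 74.2% (55.4 to 88.1), with overlapping intervals. The bithorax site on the Abd-B side was among the 33. Since all 378 sites had to be in the PitaΔZ Pita list, the strongest PitaΔZ sites missing from it could not be counted.

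A hypothesis formed after these values were seen is that the ZFP276 domain may restore the wild-type order of strength. The bound set for it was that more than 75% of the re-ordered sites have a median PitaZ276 rank on the wild-type side. The share was 84.4% (54 of 64, 73.1 to 92.2), so the interval included the bound and the test left the hypothesis open. The order in PitaZ276 was already nearer to Pitawt in the correlations above, so this share comes from the same ranks and adds no independent evidence.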
